A study of Mus musculus with 40 samples.

How the data were processed

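RNA-seq libraries of sorted mouse follicular B cells were analysed: 28 of the 40 samples that the labels list. The 8 ATAC-seq and 4 ChIP-seq samples were not analysed here. Per the labels, RNA was prepared with a column kit (RNeasy Plus Mini) and polyadenylated RNA was selected on oligo-dT beads (Dynabeads). The authors deposited the RNA-seq values as TPM, in 1 file per library with 24732 genes, and the values of every library have the same sum. Per the submitters' processing notes, the tools used across the series were TopHat 1.4.1, Bowtie, featureCounts 1.5.0, SAMtools 1.4 and deepTools 3.0.1, and the genome build was mm9. The role of each tool, the gene annotation and the strandedness of the libraries were not given in the sources used here.

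TPM keeps no depth of its own, but within a gene the values of all libraries are whole multiples of what 1 read is worth in each library. Solving for these steps gave whole reads, within a tolerance of 0.01, for 18843 of the 18843 genes above 0. The recovered totals ran from 12126702 to 25424364 reads per library. In a simulation of 8000 genes with known reads, 99.5% of those with reads in more than 1 library were recovered exactly, and the others were not counted. A gene whose reads in all libraries share a common factor is understated. The file marks 3539 genes as overlapping another gene model and 474 as having duplicated models. Reads of such genes may belong to their neighbours, and their values are uncertain. Among the genes named in the text these are Bhlhe40, Ccna2, Csf1r, Dgka, Eng, Ifi27l2a, Lck, Ltb, Nab2, Nfkb2, Plxnb2, Rasgrp4 and Rassf4. Members of near-identical families, such as Bcl2a1b and Bcl2a1d, can share reads in the same way.

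Groups were taken from the genotype and cell preparation in the labels. The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples, which may be technical in part. No pair of replicates agreed within sampling noise. Over 40 replicate pairs the chi-square per degree of freedom ran from 6.63 to 84.95. The library numbers in the titles begin with 36, 49 or 57, and these 3 beginnings are called library series below. Comparisons were kept within a library series. The chi-square of 84.95 was for a pair from different series, and within a series the highest was 54.59. In the CpG libraries the numbers form a first and a second block, each with 2 libraries per genotype, and a term for this block was an alternative.

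Each comparison was tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a mean-variance trend, a two-sided moderated test and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. Genes entered a test with a TPM of 1 or more in at least as many libraries as the smaller group has, and in at least 4 libraries for the test of the difference between CpG and HEL. Fold changes on the log2(TPM + 1) scale understate the change of genes with low TPM. All adjusted p-values in the text are from these limma fits. Values after ± beside a log2 difference are standard errors of the fit, and those beside a TPM or a percentage are standard deviations. On simulated libraries with known 2-fold changes, the test recovered 82.1% of changed genes for naive loss of Ikaros, 98.5% for HEL, 97.0% for CpG, 89.6% for anergic against naive, 97.0% for HEL exposure against naive, 100% for anergic against HEL exposure and 92.5% for the difference between CpG and HEL. Each run held 200 changed genes, and these shares are for the 67 changed 2-fold, the others being changed 1.5-fold or 4-fold. Unchanged genes were also called, 25, 8, 15, 12, 10, 13 and 4 in the same order. For naive loss, 9, 55 and 66 genes changed 1.5-fold, 2-fold and 4-fold were recovered. The 25 unchanged genes were thus a larger share of its calls than 0.05. Every simulated gene had the same dispersion of 0.02, so the shares recovered do not cover genes with a larger spread.

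Gene lists were fixed before the data were examined: 30 lists of pathways, B cell states, complexes and markers of other cell types. Each list was tested with limma's camera, with a preset correlation between genes of 0.01 and again with an estimated correlation. Of 208 tests of lists, 53 passed with the preset correlation and 1 passed with the estimated one. Counts of list members are given over all genes tested and adjusted over the list alone.

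The genes named in the text followed a rule, also fixed before the data were examined. It took Ikzf1 and Ikzf3, the 8 most raised and 8 most lowered genes per comparison, and up to 4 members per list. The first of these had to be past the threshold, with a mean TPM of at least 5 in the higher group and library values that did not overlap between groups. Antigen receptor segments and genes without a proper symbol were left out. Where no list member passed, up to 2 members with the highest TPM could be named. For the difference between CpG and HEL the rule took 5 genes per direction. Markers of other cell types could all be named. Some genes that the rule took are not reported here.

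Alternatives fixed beforehand changed the pseudocount (0.1 or 5), the filter on low TPM, the scaling of libraries (median-ratio size factors, quantile normalization, or antigen receptor segments left out), the variance model, the library weights, the control libraries and the covariates, and left out each library in turn. Alternatives chosen after the data were seen were limma's voom on the recovered reads, leaving out ribosomal protein genes, subsets of libraries by number, the block in the test of the difference, voom, median-ratio scaling and the block for the shared calls, and a term for the sex of the mice. Sex was read from Y-linked transcripts: their TPM was at most 0.06 in 8 female libraries, and Eif2s3y was at least 15.8 in 20 male libraries.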

Results

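The libraries came from FACS-sorted follicular (FO) B cells of C57BL/6 mice that carry MD4, a transgene for a B cell receptor against hen egg lysozyme (HEL). Ikaros, the zinc finger protein encoded by Ikzf1, was deleted with Cd23-cre, which is active late in B cell development. Naive cells were Cd23-cre Ikzf1(fl/-) (2 libraries), Cd23-cre Ikzf1(fl/+) (3 libraries) and Ikzf1(fl/+) without Cre (2 libraries). Cells exposed to HEL in the mouse for 1 day were Cd23-cre Ikzf1(fl/fl) or Ikzf1(fl/fl) without Cre (5 libraries each). Anergic cells (3 libraries), from mice that also carry ML5, a transgene for soluble HEL, all kept at least 1 intact Ikzf1 allele. Of these libraries 1 carries Cre and 2 do not. Cells stimulated in vitro for 1 day with CpG, a ligand of Tlr9, were Cd23-cre Ikzf1(fl/-) or Cd23-cre Ikzf1(fl/+) (4 libraries each). Depth was 12126702 to 25424364 recovered reads per library. By Y-linked transcripts 8 libraries were from female and 20 from male mice. Log2 differences are given with their standard error.

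Ikzf1 was lower in every library with loss of Ikaros than in the controls of its comparison. In naive cells it was at 65.3 and 57.3 TPM in the fl/- libraries and at 136 and 120 TPM in the fl/+ libraries of the same series. After HEL it was at 60.3 to 79.3 TPM with Cre and at 195 to 261 TPM without. After CpG it was at 31.7 to 39.5 TPM in fl/- cells and at 135 to 172 TPM in fl/+ cells. The log2 difference was -1.65 ± 0.09 with HEL (adjusted p = 1.86e-08), -1.99 ± 0.10 with CpG (adjusted p = 1.31e-05) and -1.05 ± 0.17 in naive cells, which did not pass (adjusted p = 0.0859). Anergic libraries held 304, 319 and 179 TPM, and the 3 naive controls of the same series 143 to 219 TPM. The TPM is summed over the gene and does not separate transcripts with and without the deleted part. Ikzf3, which encodes the family member Aiolos, did not pass for Ikaros loss with HEL (0.12 ± 0.09) or with CpG (-0.09 ± 0.13, and 0 without fl/+ replicate 1).

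**Figure D1:**
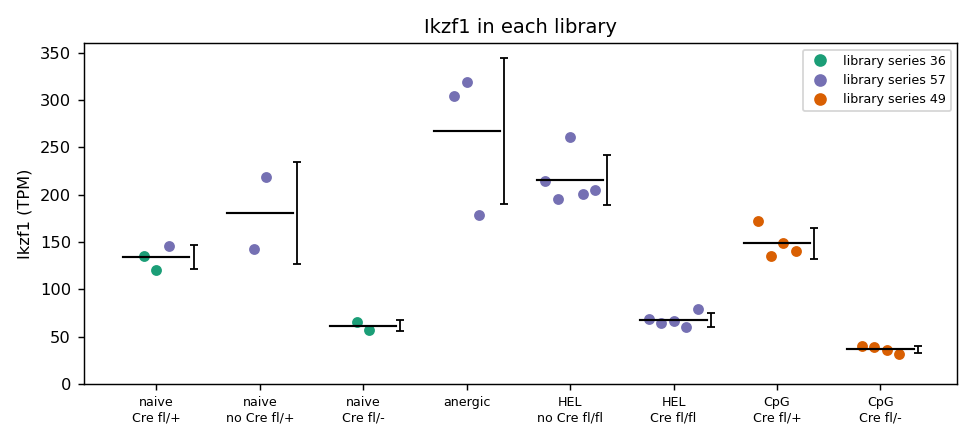
Ikzf1 TPM (vertical axis) in each of the 28 libraries, by group (horizontal axis). Points are libraries coloured by library series, lines are group means and bars are 1 SD; after HEL the Cre libraries lie between 60.3 and 79.3 TPM, below all controls (195 to 261 TPM).

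The first question was which transcripts depend on Ikaros in cells that have met antigen in the mouse. After 1 day of HEL, Ifitm2 was the most raised gene with loss of Ikaros and the lipid carrier Apoe the most lowered, among genes that the naming rule covers. Ifitm2, an interferon-inducible membrane protein, was at 83.6 ± 18.2 TPM against 2.89 ± 0.70 TPM in controls (log2 difference 4.43 ± 0.15, n = 5 and 5, adjusted p = 3.73e-10). Tmem176b was at 221 ± 14.8 against 14.6 ± 3.4 TPM (3.86 ± 0.12), and its neighbour Tmem176a (4.02 ± 0.10), the TGF-beta co-receptor Eng (4.14 ± 0.11), Aif1 (3.71 ± 0.21), Slamf9 (3.60 ± 0.10), the catenin Ctnnd1 (3.57 ± 0.10) and Dkkl1 (3.56 ± 0.14) rose by similar amounts. Apoe was at 9.81 ± 2.61 against 196 ± 43.2 TPM (-4.19 ± 0.17, adjusted p = 1.33e-09). Next among lowered genes were Stac2 (-2.31 ± 0.12), the MAP kinase phosphatase Dusp4 (-2.27 ± 0.21), Mapk12 (-2.13 ± 0.20), the calcium channel Cacna1i (-2.06 ± 0.15), Myo1f (-1.99 ± 0.11) and the signalling adaptor Tyrobp (-1.92 ± 0.13).

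Genes of the immediate early response were lower with loss of Ikaros after HEL. Of 18 tested members 14 were lower, 0 higher and 4 did not pass (15 lower adjusted over the list alone; camera adjusted p = 0.000438, but adjusted p = 0.532 with an estimated correlation). Among them were the nuclear receptor Nr4a1 (-1.90 ± 0.21), Dusp2 (-1.15 ± 0.13), the activation marker Cd69 (-1.10 ± 0.15) and Zfp36, which promotes mRNA decay (-0.82 ± 0.08). Of 24 genes for Myc and ribosome biogenesis, 20 were lower, 1 higher and 3 did not pass (20 and 1 adjusted over the list alone; camera adjusted p = 3.94e-06, but adjusted p = 0.594 with an estimated correlation), including the spermidine synthase Srm (-1.16 ± 0.12), Nop58 (-0.68 ± 0.08), Rrp9 (-0.66 ± 0.06) and Rrs1 (-0.62 ± 0.06). Of 22 mature B cell identity genes 13 were lower, 4 higher and 5 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.0153, but adjusted p = 0.604 with an estimated correlation). They included the complement regulator Cd55 (-1.09 ± 0.11), S1pr1 (-1.03 ± 0.12), Satb1 (-0.91 ± 0.07) and the follicle-homing receptor Cxcr5 (-0.65 ± 0.07). All 5 tested early B cell genes were higher, also adjusted over the list alone (camera adjusted p = 0.000974, but adjusted p = 0.25 with an estimated correlation), among them Myb (0.97 ± 0.15), Erg (0.90 ± 0.14), Cd93 (0.78 ± 0.20) and Vpreb3 (0.50 ± 0.11).

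Signalling lists moved both ways with loss of Ikaros after HEL. Of 34 genes of BCR signalling 5 were higher and 11 lower, and the split was 8 and 8 with median-ratio scaling. Dok3, an adaptor that restrains the receptor, had the smallest adjusted p among them and was lower (-1.39 ± 0.05), Cd79a was lower (-0.37 ± 0.06), and Vav3 (0.66 ± 0.11) and Bcl10 (0.39 ± 0.06) were higher. Of 28 genes of TLR signalling 4 were higher and 7 lower, which turned to 6 and 4 with median-ratio scaling. Tlr2 was higher (1.12 ± 0.08), and Sigirr, a negative regulator of Toll-like receptors, was lower (-0.42 ± 0.05). Of 23 NF-kB targets 5 were higher and 7 lower, or 5 and 4 with median-ratio scaling, with Gadd45b (-1.70 ± 0.09) and the kinase Pim1 (-1.55 ± 0.11) lower and Nfkb2 (0.46 ± 0.07) higher. Of 25 genes of the B cell anergy list 8 were higher and 9 lower. Pcp4 (2.79 ± 0.18), the inhibitory receptor gene Pdcd1 (2.14 ± 0.16) and Spry2 (1.45 ± 0.11) were higher, and the diacylglycerol kinase Dgka was lower (-0.72 ± 0.07). Adjusted over the list alone, higher and lower counts were 5 and 11 for BCR signalling, 4 and 7 for TLR signalling, 5 and 7 for NF-kB targets and 8 and 10 for anergy. None of these 4 lists passed camera, with adjusted p = 0.953, 0.952, 0.953 and 0.64.

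Of 13 tested myeloid and dendritic cell markers 7 were higher in the same cells. Of 8 tested myeloid markers 3 were higher: Cd68 (8.18 to 24.5 TPM, 1.48 ± 0.13), Csf1r (0.43 to 2.94 TPM, 1.44 ± 0.15) and Ccl6 (0.42 ± 0.09). Camera gave an adjusted p of 0.000754 (adjusted p = 0.25 with an estimated correlation). Of 5 dendritic cell markers 4 were higher: Siglech (0.0153 to 1.95 TPM, 1.52 ± 0.12), Cd209a (1.47 ± 0.13), Flt3 (4.26 to 12.2 TPM, 1.33 ± 0.17) and Zbtb46 (0.42 ± 0.13). Camera gave an adjusted p of 0.000754 (adjusted p = 0.117 with an estimated correlation). Zbtb46 lost its call without Cre replicate 4 (0.35) or 5 (0.38), or without control replicate 1 (0.37) or 2 (0.40). Over all genes, 3790 of 10258 were called, 1321 higher and 2469 lower, and 335 changed at least 2-fold. The split was 1824 higher and 1642 lower with median-ratio scaling, and 1843 and 1653 with voom on the recovered reads. The controls carry no Cre, so the presence of Cre and the loss of Ikaros go together in this comparison.

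With CpG in vitro, both arms carried Cre and the controls had 1 intact Ikzf1 allele. Loss of Ikaros again raised Tmem176b (288 ± 14.0 against 7.41 ± 2.18 TPM, log2 difference 5.14 ± 0.15, n = 4 and 4, adjusted p = 4.62e-07), Tmem176a (4.65 ± 0.16), Ifitm2 (279 ± 51.0 against 26.9 ± 6.32 TPM, 3.34 ± 0.18) and Eng (3.29 ± 0.09). Pdcd1, which encodes PD-1, was at 16.6 ± 7.10 against 0.89 ± 0.80 TPM (3.23 ± 0.34, adjusted p = 0.00051), and Rassf4 (3.09 ± 0.12) and Cd300e (3.01 ± 0.16) were also among the most raised. Among the most lowered were the adaptor Scimp (-2.03 ± 0.29), Ms4a4b (-2.01 ± 0.27), Utf1 (-1.86 ± 0.22), the adhesion molecule Cd2 (-1.79 ± 0.21) and the cytokine gene Ltb (-1.74 ± 0.27). Over all genes 1551 of 10386 were called, 949 higher and 602 lower, and 277 changed at least 2-fold. With the library-number block as a term the count was 2221, and it was 909 without fl/- replicate 3.

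Among the genes of B cell identity, receptor signalling and costimulation that passed after CpG, most were lower with loss of Ikaros. Of 22 mature B cell identity genes 14 were lower, 0 higher and 8 did not pass (14 lower and 1 higher adjusted over the list alone; camera adjusted p = 2.5e-07, but adjusted p = 0.406 with an estimated correlation). In fl/+ replicate 1 the mean level of this list stood above the other controls (6.856 against 6.536 to 6.564), which widens the difference, and the genes named next kept their calls without it. Examples were Satb1 (-1.06 ± 0.11), the chemokine receptors Ccr7 (-0.96 ± 0.14) and Cxcr5 (-0.73 ± 0.10), and the BAFF receptor gene Tnfrsf13c (-0.60 ± 0.09). Of 34 genes of BCR signalling 13 were lower, 1 higher and 20 did not pass (17 and 3 adjusted over the list alone; camera adjusted p = 2.74e-06, but adjusted p = 0.406 with an estimated correlation), including the inhibitory co-receptor Cd22 (-0.87 ± 0.09), Pik3ap1 (-0.73 ± 0.10), the kinase Lyn (-0.56 ± 0.08) and the phosphatase Ptprc (-0.53 ± 0.09). Of 23 genes of activation and costimulation 9 were lower, 1 higher and 13 did not pass (13 and 1 adjusted over the list alone; camera adjusted p = 2.74e-06, but adjusted p = 0.31 with an estimated correlation). They included Pdcd1lg2 (-1.16 ± 0.17), H2-Ob (-1.13 ± 0.14), the class II gene H2-Eb1 (-0.86 ± 0.17) and the ICOS ligand gene Icosl (-0.82 ± 0.09).

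Of 28 genes of TLR signalling 6 were lower and 2 higher after CpG (7 and 2 adjusted over the list alone; camera adjusted p = 0.0063, but adjusted p = 0.406 with an estimated correlation). The lowered members included Tlr9, the receptor for CpG DNA (-0.84 ± 0.12), and inhibitors of the pathway, the ubiquitin-editing enzyme Tnfaip3 (-1.11 ± 0.13) and Irak3 (-1.09 ± 0.13). Of 25 NF-kB targets 9 were lower and 1 higher (10 and 1 adjusted over the list alone; camera adjusted p = 0.00118, but adjusted p = 0.31 with an estimated correlation), with Bcl2a1d (-1.29 ± 0.24) and Traf1 (-1.19 ± 0.19) lower and the chemokine gene Ccl3 higher (1.46 ± 0.23). Of 19 immediate early genes 6 were higher and 0 lower (6 and 5 adjusted over the list alone, and 6 and 5 with the block), including Ier3 (0.82 ± 0.12), Egr1 (0.81 ± 0.12) and Nr4a1 (0.73 ± 0.10); camera did not pass (adjusted p = 0.488). Of 32 proliferation genes 6 were higher and 0 lower (13 higher adjusted over the list alone, 17 higher with the block; camera adjusted p = 1.53e-05, but adjusted p = 0.684 with an estimated correlation), such as Ccna2 (0.87 ± 0.17) and Bub1b (0.46 ± 0.10). The plasma cell genes Sdc1 (1.70 ± 0.13) and Fkbp11 (1.30 ± 0.20) were higher in a list with 4 higher and 2 lower of 20, with the same counts adjusted over the list alone. Of the early B cell genes Igll1 (2.30 ± 0.21), Il7r (1.22 ± 0.17) and Myb (1.05 ± 0.08) were higher, 3 of 6 tested, with 1 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.12). None of 30 interferon-stimulated genes was called by limma (0 adjusted over the list alone), with a median log2 difference of -1.40 and a wide spread between libraries; voom also called 0, and 11 were lower with the block. Neutrophil transcripts varied among these libraries, with S100a9 at 1.95 TPM in fl/- and 13.7 TPM in fl/+ cells; it did not pass, and the log2 difference was 0.22 without fl/+ replicate 4.

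**Figure D2:**
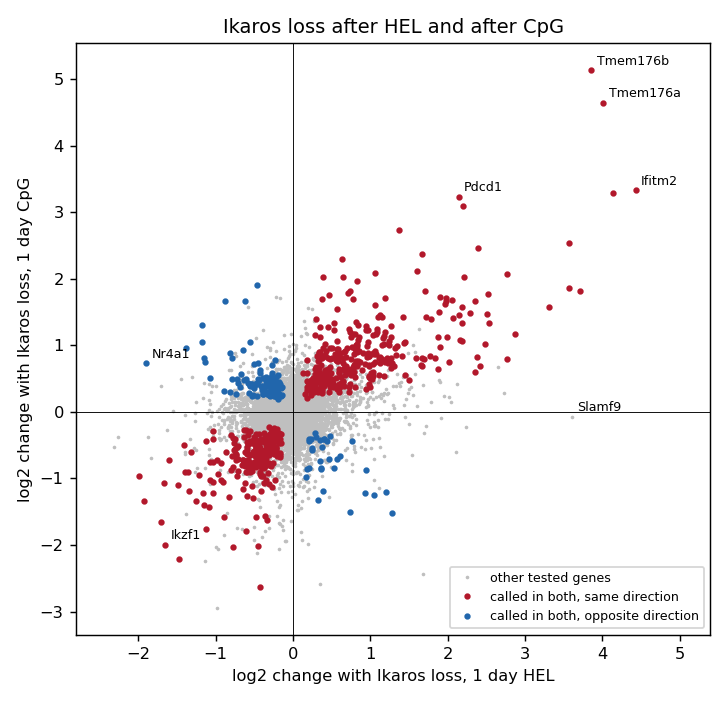
Log2 differences with loss of Ikaros for each gene tested in both settings, after HEL (horizontal axis) and after CpG (vertical axis), with named genes marked. Points are genes; Tmem176b (3.86 and 5.14) and Ifitm2 (4.43 and 3.34) lie high on both axes, and Nr4a1 is lower after HEL (-1.90) and higher after CpG (0.73).

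The effect of Ikaros loss was then compared between settings, which differ in stimulus, culture, library series and genotype of the controls. Of 9733 genes tested in both, 325 were called higher in both, where independent lists give 96.9 (odds ratio 6.51, Fisher's exact p = 6.08e-105). Called lower in both were 255 genes, where independent lists give 139.6 (odds ratio 2.66, Fisher's exact p = 2.04e-27). Without CpG fl/- replicate 3 the count was 147, but the genes called lower with CpG then fell from 602 to 322. The 139.6 is for all libraries and does not apply to that count. With all libraries, a further 154 genes were called in opposite directions. Across genes, which are not independent replicates, the 2 sets of log2 differences correlated with Pearson's r = 0.402 and Spearman's rho = 0.214. In a test of the difference, CpG minus HEL, 2479 of 11050 genes were called, 1685 higher and 794 lower, or 1353 and 1067 with median-ratio scaling. The 11050 genes include some under the TPM minimum in at least 1 setting, since 9733 were tested in both. For those a difference can reflect low expression in that setting and not an unlike effect of Ikaros loss. The effect of Ikaros loss was higher with CpG for Apoe (3.24 ± 0.36), Cd300e (2.96 ± 0.17), Gas7 (2.81 ± 0.17) and Nr4a1 (2.63 ± 0.28). It was lower for Slamf9 (-3.68 ± 0.40), the properdin gene Cfp (-2.8 ± 0.46) and Pcp4 (-2.61 ± 0.25), though Pcp4 was not called with voom. Of 20 immediate early genes 12 had a higher effect with CpG and 0 a lower one (12 and 2 adjusted over the list alone; camera adjusted p = 0.00372, but adjusted p = 0.333 with an estimated correlation). Of 24 Myc and ribosome biogenesis genes 14 had a higher effect and 0 a lower one (16 and 0 adjusted over the list alone; camera adjusted p = 2.37e-07, but adjusted p = 0.333 with an estimated correlation). Of 24 activation and costimulation genes 9 had a lower effect and 1 a higher one (12 and 1 adjusted over the list alone; camera adjusted p = 1.12e-05, but adjusted p = 0.107 with an estimated correlation). For TLR signalling it was 6 lower and 1 higher of 28, also adjusted over the list alone (camera adjusted p = 0.00578, but adjusted p = 0.333 with an estimated correlation).

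Naive cells with and without Ikaros could be compared within 1 library series with 2 libraries on each side. Ms4a6c (log2 difference 2.00 ± 0.21) and Tmem176b (130 ± 30.8 against 35.0 ± 0.84 TPM, 1.84 ± 0.20) were higher, both with an adjusted p of 0.0483, and no other gene of 10053 was called. At an unadjusted p under 0.05 there were 896 genes, and voom on the recovered reads called 58. Leaving out either fl/- or either fl/+ library ended both calls (Ms4a6c at 1.90 to 2.10, Tmem176b at 1.60 to 2.09). Plac8 (1.2 ± 0.19, adjusted p = 0.0859), the growth factor receptor Flt3 (1.57 ± 0.32, adjusted p = 0.123) and Bhlhe40 (-1.44 ± 0.33, adjusted p = 0.162) did not pass. With a term for sex, which is balanced here, 240 genes were called and these 3 passed. The median over all genes was -0.12. Of the genes called in the same direction with HEL and CpG and tested here, 242 of 305 higher ones (79.3%) and 228 of 249 lower ones (91.6%) had the same sign in naive cells. The negative median of all genes raises the share for the lower ones and reduces that for the higher ones. These libraries held transcripts of other cells that the naive libraries of the other series lacked, such as Gzma, a cytotoxic granule protease, at 14.4 TPM in fl/- cells, 12.2 TPM in the fl/+ libraries compared with them and 0 in the 3 controls of series 57.

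Anergic cells were set against naive cells of the same series, 3 libraries on each side, to describe B cells that live with their antigen. The antigen-response regulators Egr3 (log2 difference 3.98 ± 0.16, adjusted p = 2.76e-05), Egr2 (3.42 ± 0.19), Nr4a1 (3.26 ± 0.26) and Nr4a3 (3.09 ± 0.17) were higher, together with the stress-inducible gene Ndrg1 (4.41 ± 0.24), Ephx1 (3.27 ± 0.14), Rgl1 (3.24 ± 0.13) and Sdc1, which encodes CD138 (3.24 ± 0.20). Nrgn, a calmodulin-binding protein, was at 143 ± 82.2 against 8.17 ± 0.52 TPM (3.83 ± 0.32). The most lowered were Lrrc25 (-2.99 ± 0.13), S100a6 (-2.98 ± 0.24), Lurap1 (-2.50 ± 0.25), the arginine-synthesis enzyme Ass1 (-2.38 ± 0.22), Amz1 (-2.20 ± 0.14) and Rap1gap2 (-2.19 ± 0.15). Over all genes 775 of 10519 were called, 471 higher and 304 lower, or 409 and 444 with median-ratio scaling; 306 changed at least 2-fold. The count was 323 without naive no-Cre replicate 1, 381 without naive no-Cre replicate 2, 394 without naive Cre replicate 3, 353 without anergic replicate 1, and 417 with Cre as a covariate.

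Of 24 genes of the anergy list 10 were higher, 1 lower and 13 did not pass in anergic cells (13 and 2 adjusted over the list alone; camera adjusted p = 8.58e-05, but adjusted p = 0.548 with an estimated correlation), including Nab2, a co-repressor of Egr proteins (2.76 ± 0.18). Of 6 early B cell genes 4 were higher and 1 lower (4 and 1 adjusted over the list alone; camera adjusted p = 0.0138, but adjusted p = 0.758 with an estimated correlation), with Lef1 (3.01 ± 0.24), Myb (2.63 ± 0.28) and Sox4 (2.28 ± 0.31) higher. Of 23 NF-kB targets 6 were higher and 2 lower (9 and 2 adjusted over the list alone; camera adjusted p = 0.0403, but adjusted p = 0.758 with an estimated correlation), with Ccl4 (2.89 ± 0.36) and Bcl2a1b (2.03 ± 0.26) higher and Pim1 lower (-1.42 ± 0.21). The survival gene Bcl2 (1.51 ± 0.12) and the death gene Bcl2l11 (1.28 ± 0.15) were the 2 members of 19 called in the cell death list, both higher (4 adjusted over the list alone). Of 29 interferon-stimulated genes 10 were lower and 0 higher (19 lower adjusted over the list alone; camera adjusted p = 6.75e-16, but adjusted p = 0.548 with an estimated correlation), among them Oas3 (-1.84 ± 0.22), Oasl1 (-1.27 ± 0.11) and Irf7 (-1.26 ± 0.15). In TLR signalling Irak3 (-0.96 ± 0.11) and Irf7 were lower and 25 of 27 did not pass (2 lower adjusted over the list alone). Lck, a kinase best known from T cells, was at 97.0 ± 17.9 against 11.8 ± 3.71 TPM (2.96 ± 0.23), while the T cell gene Cd3e was at 0.0325 TPM in anergic cells. Of 3 dendritic cell markers 2 were lower (2 adjusted over the list alone; camera adjusted p = 0.0473, but adjusted p = 0.548 with an estimated correlation), and 1 of these, Bst2, is also an interferon-stimulated gene.

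**Figure D3:**
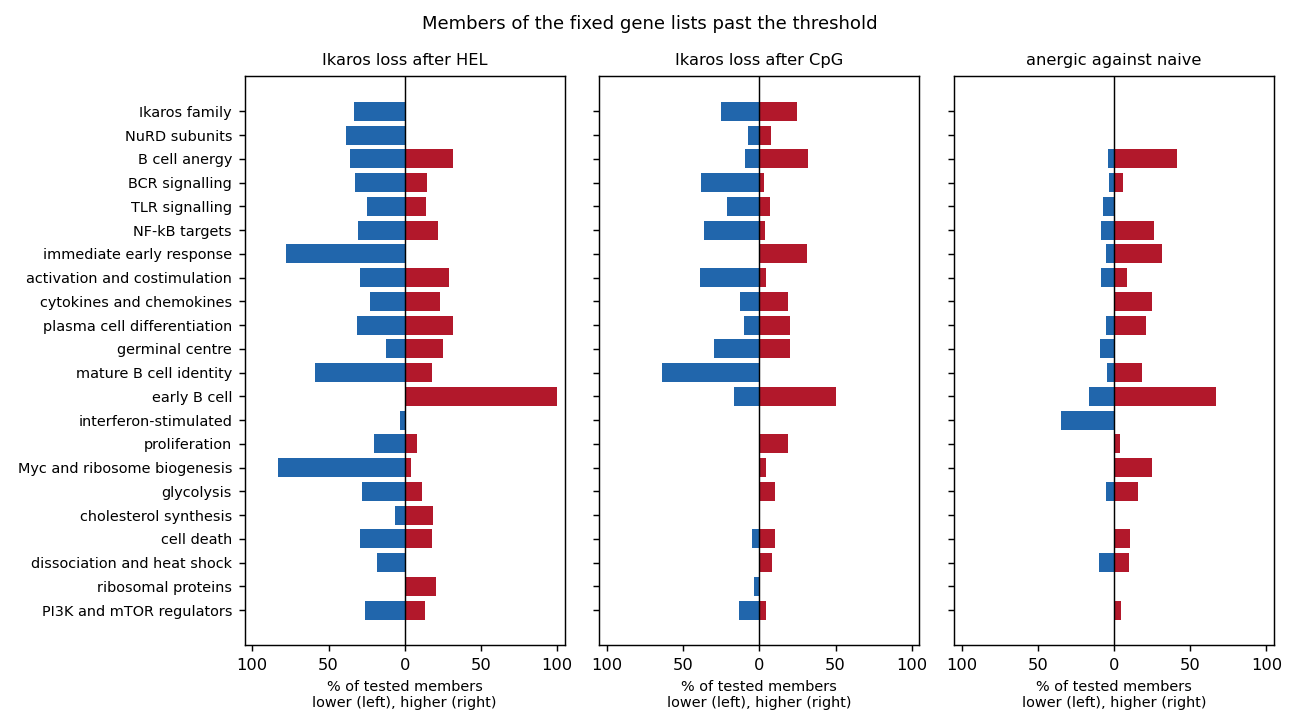
Percent of tested members of 22 fixed lists called higher (right) or lower (left) for Ikaros loss after HEL, Ikaros loss after CpG and anergic against naive cells, with 1 bar per list and direction. With TPM as deposited, immediate early genes are lower in 14 of 18 after HEL and higher in 6 of 19 after CpG, and 10 of 24 anergy genes are higher in anergic cells; the split of TLR signalling after HEL, 4 higher and 7 lower, turns to 6 and 4 with median-ratio scaling.

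One day of HEL in cells without Cre was compared with the naive controls of the same series (5 against 3 libraries). Genotype differs between the sides, fl/fl against fl/+, and 1 of the 3 naive controls carries Cre. Ribosomal protein transcripts took 22.8 ± 0.85% of all TPM after HEL and 15.0 ± 0.61% in these naive cells. Of the 29 ribosomal protein genes in the list 25 were higher, 0 lower and 4 did not pass (26 higher adjusted over the list alone; camera adjusted p = 2.11e-26, and adjusted p = 0.0462 with an estimated correlation), such as Rplp0 (1.15 ± 0.07), Rpl3 (0.90 ± 0.07) and Rps18 (0.79 ± 0.06). Of 11 genes of dissociation and heat shock, which respond to the handling of cells, 3 were higher and 0 lower (3 adjusted over the list alone; camera adjusted p = 0.00199, but adjusted p = 0.926 with an estimated correlation): Hspa8 (1.07 ± 0.12), Hspe1 (0.96 ± 0.07) and Hspd1 (0.30 ± 0.06). The naive libraries of the other series held 20.2 to 24.5% of TPM in ribosomal protein transcripts, close to the HEL libraries. TPM sums to the same total in every library, so a larger share for some genes lowers the others, and the median of all genes was -0.16. Of 10448 genes 5015 were called, 1036 higher and 3979 lower, but 2087 and 2118 with median-ratio scaling and 2021 and 2190 with voom. With all 5 naive controls of both series the count was 2179.

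Among single genes after 1 day of HEL, Nrgn (53.4 ± 6.28 TPM, 2.56 ± 0.09), Ephx1 (2.60 ± 0.11), Sdc1 (2.45 ± 0.13), Nab2 (2.17 ± 0.18), Egr3 (1.96 ± 0.16) and Egr2 (1.28 ± 0.19) were higher, as were the G protein regulator Rgs10 (3.25 ± 0.27), the chemokine gene Ccl4 (2.71 ± 0.19), Lck (2.40 ± 0.20) and Sp140 (2.14 ± 0.21). Of 24 anergy genes 11 were higher, 5 lower and 8 did not pass (11 and 6 adjusted over the list alone, 12 and 2 with median-ratio scaling; camera adjusted p = 0.000198, but adjusted p = 0.532 with an estimated correlation). Of 19 immediate early genes 4 were higher and 5 lower (4 and 5 adjusted over the list alone, 5 and 3 with median-ratio scaling; camera adjusted p = 0.348). Of 34 genes of BCR signalling 3 were higher and 13 lower (3 and 13 adjusted over the list alone, 12 and 8 with median-ratio scaling; camera adjusted p = 0.886). The most lowered were Rnd3 (-2.65 ± 0.26), S100a6 (-2.59 ± 0.21), Hivep3 (-2.55 ± 0.12), Lrrc25 (-2.54 ± 0.12), Ccdc88b (-2.43 ± 0.14) and Rasgrp4 (-2.20 ± 0.12). Also lower was C1qa, a complement gene of macrophages (1.04 against 8.44 TPM, -2.15 ± 0.23). Of 12 germinal centre genes 10 were lower and 0 higher (11 lower adjusted over the list alone, 8 with median-ratio scaling), such as Plxnb2 (-1.66 ± 0.13); camera did not pass (adjusted p = 0.0876). Ikzf3 was lower (-0.48 ± 0.08), and Ikzf1 missed the threshold (0.37 ± 0.14, adjusted p = 0.0524) but passed with median-ratio scaling (0.54) or without naive no-Cre replicate 2 (0.56). Of 31 interferon-stimulated genes 14 were higher and 0 lower (9 adjusted over the list alone; camera adjusted p = 5.07e-11, but adjusted p = 0.926 with an estimated correlation), such as Ifi27l2a (1.73 ± 0.35) and Ifit3 (1.95 ± 0.49). The HEL libraries were from 3 female and 2 male mice and the naive ones all from males. With a term for sex 2 of the 31 were higher, the median fell from 0.98 to 0.36, and Ifit3 was no longer called (1.09). This term rests on the 3 female and 2 male HEL libraries. The mean log2 level of the list was 5.44 to 6.254 in the females, 5.269 and 3.981 in the males, and 4.22 to 4.312 in the naive controls. Only 1 HEL male was low, so whether sex accounts for the difference stays open.

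**Figure D4:**
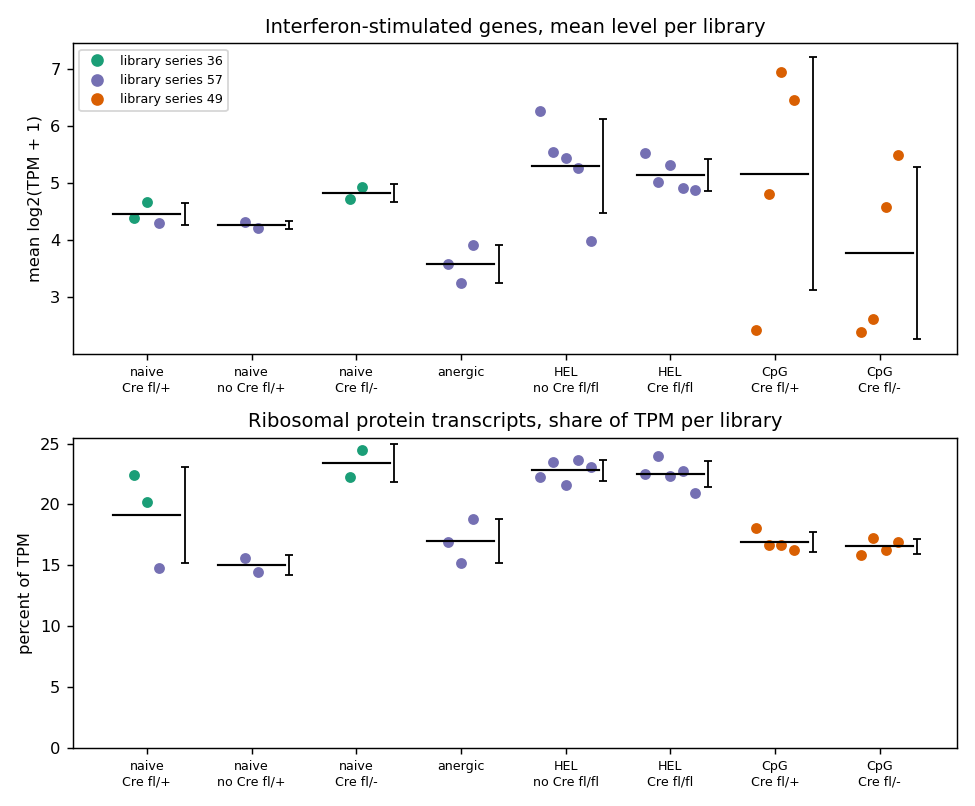
Mean log2(TPM + 1) of the interferon-stimulated list and percent of TPM in ribosomal protein genes (vertical axes) in each library, by group (horizontal axes). Points are libraries, lines are means and bars are 1 SD; the interferon list runs from 3.98 to 6.25 in HEL controls, from 3.24 to 3.92 in anergic cells and from 2.39 to 6.95 after CpG.

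Anergic cells were also compared directly with cells exposed to HEL for 1 day (3 against 5 libraries). Of the anergic libraries 1 carries Cre and 2 do not, while all HEL libraries are fl/fl without Cre, so genotype also differs between the sides. Higher in anergic cells were Ndrg1 (4.14 ± 0.23), Pcp4 (3.20 ± 0.34), Rgl1 (2.59 ± 0.16), the receptor F2rl1 (2.41 ± 0.24), Egr2 (2.14 ± 0.16) and Egr3 (2.02 ± 0.15). All 6 tested early B cell genes were higher, also adjusted over the list alone (camera adjusted p = 1.86e-05, but adjusted p = 0.243 with an estimated correlation), including Sox4 (2.78 ± 0.22), Lef1 (2.68 ± 0.14), Myb (2.43 ± 0.24) and Cd93 (2.00 ± 0.15). Part of this was a fall after HEL. Against naive cells, 3 of 4 tested genes of this list were lower after HEL and 0 higher. The log2 difference from naive cells was 0.93 in anergic and -1.07 in HEL cells for Cd93, and -0.83 and -1.85 for Vpreb3. Of 25 anergy genes 13 were higher and 3 lower (14 and 3 adjusted over the list alone, 9 and 4 with median-ratio scaling; camera adjusted p = 0.395). Lower were Sdc3 (-2.66 ± 0.53), Rgs10 (-2.56 ± 0.32) and Alox5ap, which serves leukotriene synthesis (-2.50 ± 0.29). Of 31 interferon-stimulated genes 27 were lower and 0 higher (27 adjusted over the list alone; camera adjusted p = 6.45e-28, but adjusted p = 0.385 with an estimated correlation), such as Isg15 (-3.03 ± 0.55), Oas3 (-2.77 ± 0.59), Ifit3 (-2.68 ± 0.56) and Oas1a (-2.56 ± 0.51). With a term for sex, which rests on the 3 female and 2 male HEL libraries, 11 were lower. Of 29 ribosomal protein genes 17 were lower and 0 higher (17 adjusted over the list alone; camera adjusted p = 5.86e-20, but adjusted p = 0.243 with an estimated correlation), such as Rplp0 (-0.86 ± 0.09), and their share of TPM was 17.0 ± 1.80% in anergic cells. Of 11 genes of dissociation and heat shock 2 were lower and 0 higher (2 adjusted over the list alone; camera adjusted p = 0.000906, but adjusted p = 0.685 with an estimated correlation), Hspa8 (-0.81 ± 0.22) and Hspe1 (-0.63 ± 0.19). The Y-linked gene Kdm5d was called (2.30 ± 0.78) and was not with a term for sex (0.41), since the anergic libraries were all from males. Of 10491 genes 4425 were called, 3860 higher and 565 lower, but 1168 and 1329 with median-ratio scaling. The median of all genes was 0.23, and the count was 2800 without anergic replicate 1.

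Anergic and HEL cells shared their naive controls. Of 10336 genes tested against naive in both, 209 were called higher in both (independent lists give 42.3), 251 lower in both (117) and 41 in opposite directions. The log2 differences correlated across genes at 0.553, and at 0.557 in 100 simulations of unchanged groups against the same controls. The simulated value is set by the group sizes, and the simulations hold no changed genes. The correlation therefore cannot tell whether changes are shared. The covariance was 0.0899, and 0.0158 in the simulations. The 3 controls are too few to be split, so part of the excess may come from sharing them.

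The genes that distinguish anergic from naive cells were followed under Ikaros loss, in libraries that had no part in choosing them. Of genes lower in anergic cells, 290 could be tested with HEL, where 128 were higher and 51 lower with loss of Ikaros. Their median lay 0.24 above that of all genes (camera adjusted p = 7.08e-12, and adjusted p = 0.0116 with an estimated correlation), 0.149 above with quantile normalization and 0.55 above in the set of 2-fold changes alone. Of genes higher in anergic cells, 434 could be tested, where 78 were higher and 173 lower with loss, among them Nr4a1 (-1.90 ± 0.21). Their median was lower by 0.09 (camera adjusted p = 0.0914). With CpG neither set passed (adjusted p = 0.0748 for 265 genes lower in anergic cells and 0.0847 for 402 higher ones). In naive cells, tested after the other results were seen, the lower set lay 0.21 above all genes (camera adjusted p = 2.16e-10, but adjusted p = 0.187 with an estimated correlation). The higher set was lower by 0.16 (camera adjusted p = 1.44e-05, but adjusted p = 0.308 with an estimated correlation).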

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

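The tests of other cells in the sort and of the interferon-stimulated genes among the CpG libraries were chosen only after the results were seen. For the other tests and all splits of the libraries, what each explanation would show was written before the result of the test, though leaving out ribosomal protein genes was an idea from the data. In groups of 4 or 5 libraries, 39 measures were examined for a library far from the others, and 5 of 156 tests found one; chance alone does so in about 1 in 20. After HEL, control replicate 3 held 260.8 TPM of Ikzf1 against 195.0 to 214.0 in the others (gap 0.711 of the range), and 0.047 TPM of Pdcd1 against 0 in the others (gap 1 of the range). After CpG, fl/+ replicate 1 stood apart in the mean log2 level of mature B cell identity genes (6.856 against 6.536 to 6.564, gap 0.912) and of PI3K and mTOR regulators (4.629 against 4.432 to 4.441, gap 0.954). After CpG, fl/- replicate 4 stood apart in the cell death list (5.314 against 5.399 to 5.409, gap 0.895).

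The effect of Ikaros loss differed between CpG and HEL, by limma's test of the difference, for 2479 genes. Among those named by the rule were Apoe (3.24), Cd300e (2.96), Il27 (2.86), Gas7 (2.81), Nr4a1 (2.63), Slamf9 (-3.68), Cfp (-2.8), Pcp4 (-2.61) and Mt1 (-2.47). Mt1 lost its call without CpG fl/+ replicate 3 (-1.96) or 4, and Mt1, Il27 and Pcp4 were not called with voom. By camera with the preset correlation, the lists that differed had median differences of -0.204 for BCR signalling, -0.111 for TLR signalling, -0.234 for NF-kB targets, 0.682 for immediate early genes, -0.539 for activation and costimulation, -0.169 for mature B cell identity, -0.665 for marginal zone markers, -1.168 for interferon-stimulated genes, 0.339 for proliferation, 0.58 for Myc and ribosome biogenesis, -0.784 for myeloid markers, -1.062 for dendritic cell markers and -0.113 for ribosomal proteins. None of these lists passed with an estimated correlation. Some tested genes were hardly expressed in 1 setting, where their effect is bound to be small on the log2(TPM + 1) scale. After CpG, Siglech was at 0.026 TPM in fl/- and 0 in fl/+ cells, Cd209a at 0.085 and 0, and Csf1r at 0.288 and 0.159. Flt3, at 32.9 and 18.4 TPM, was well expressed there. For genes at such low levels the difference does not show an unlike effect of Ikaros loss.

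Other splits of the libraries into groups of the same sizes were counted. For Ikaros loss with HEL, the difference between CpG and HEL, and genes called alike, only a random sample of splits was run, 100 with the real one. Chance can be excluded for Ikaros loss with HEL (3790 calls, highest other split 2), HEL exposure against naive (5015, 7) and anergic against HEL exposure (4425, 6). In each, only 1 of the splits run, the real one, gave as large a result. For Ikaros loss with CpG it can also be excluded (1551 calls). The highest other split there, with 19, follows the library-number block, and 2221 genes were called with the block as a term. For the difference between CpG and HEL (2479, 821) and genes called alike in both settings (580, 0), the real split also gave the largest result. These splits break up the effect in both settings, so they cannot tell whether the effects differ or overlap beyond independent lists. Other splits gave at most 2 calls with HEL and 19 with CpG, so genes called alike were bound to be few. For anergic against naive the 10 splits are too few for such a share (775 calls, highest other 0). For the genes higher in anergic cells, the real split gave the largest distance of their median from all genes with HEL (0.086, highest other 0.072) and with CpG (0.071, 0.057). This bears only on how the libraries were grouped. Against other genes this set did not pass (camera adjusted p = 0.0914 with HEL and 0.0847 with CpG). For the genes lower in anergic cells the real split was also the largest run with HEL (0.239, 0.214) but not with CpG, where 14 of 35 splits gave a distance as large as 0.082, up to 0.181. With HEL the margins were narrow, and splits not run could match them. No adjustment was made for the number of these tests of anergy genes, so they do not by themselves exclude chance.

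Of the genes called after HEL exposure against naive, 20.7% were higher. Reads per library do not account for this, since with every library thinned to the same number of reads the share was 20.5%. Antigen receptor segments do not either, since without them it was 16.3%. Without ribosomal protein genes it was 42.5%, consistent with part of the lower calls coming from the larger ribosomal protein share of a fixed total. Whether that share reflects HEL stays open: the naive libraries of series 36 held 20.2 to 24.5%, close to HEL libraries, 3 of 11 dissociation and heat shock genes were also higher after HEL, and no test here separates HEL from differences in handling.

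Of 13 tested myeloid and dendritic cell markers 7 were higher with Ikaros loss after HEL; camera did not pass with an estimated correlation (adjusted p = 0.25 and 0.117). The test of other cells in the sort took all tested markers to rise together: 12 of 13 were higher, with a median of 0.54, between the bounds set for and against. The markers belong to several cell types, and cells of 1 type need not raise them all. The pooled median therefore cannot decide, and whether other cells brought these transcripts stays open. An earlier version of the test, on 15 markers that had not risen, gave a median of 0.07 with 9 higher; it left out the called genes and held genes near the floor, and decides nothing. Whether loss of Ikaros itself raises these genes stays open too: 7 of the 7 risen ones had a higher mean with loss after CpG, but 5 lay under the TPM minimum there, so the count decides nothing. Of the 2 that could be tested 1 passed, Flt3 (0.86), which lost its call without fl/- replicate 1 (0.79), 2 (0.89) or 3 (0.83) or fl/+ replicate 3 (0.79) or 4 (0.68). Lyz2, abundant in myeloid cells, was at 2.51 against 1.24 TPM.

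Interferon-stimulated genes differed widely among CpG libraries. The mean log2 level of the list was higher in the second library-number block by 2.53 in fl/- cells and 3.09 in fl/+ cells, consistent with a difference between the blocks, for which the exact permutation p was 0.0571. A lower level with loss of Ikaros may add to it: with the block as a term 11 of 30 genes were lower and 0 higher, and the genotype difference was -1.67 in the second block. In the first block it was -1.11, but this rests on fl/+ replicate 2 (4.8), since fl/+ replicate 1 (2.431) lay between the fl/- libraries (2.391 and 2.618), so the first block adds no support. Without the block the exact permutation p for genotype was 0.286.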

How the results depend on the processing

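The settings chosen only after results were seen were voom, ribosomal protein genes left out, the first 8 HEL and the first or last 4 CpG libraries, the block in the difference and in the shared calls, median-ratio scaling of the shared calls, and the term for sex. Ikaros loss with HEL, the difference between CpG and HEL, and genes higher in both settings at any fold change kept their counts within 1.5 times under every setting run; leaving out 1 library gave 3262 to 3764 calls with HEL. The causes of the moves below were not tested. Naive loss (2 calls) gave 0 with pseudocount 0.1, with no filter, with all 3 Cre fl/+ libraries and with all 7 naive libraries, 13 with a mean TPM of 5, 17 with median-ratio scaling, 9 with quantile normalization, 10 without antigen receptor segments, 30 with robust estimation, 418 in one fit over all libraries, 58 with voom, 11 without ribosomal protein genes, 240 with sex, and 0 to 0 without 1 library, where a lone library is assumed to vary like the other group. CpG loss (1551) gave 3323 with array weights, 2379 in one fit over all libraries, 272 in the first and 2388 in the last 4 libraries, and 909 (without fl/- replicate 3) to 1907 without 1 library. Anergic against naive (775) gave 3175 with array weights, 1314 in one fit over all libraries, 417 with Cre as a covariate, and 323 (without naive no-Cre replicate 1) to 1153 without 1 library. HEL exposure against naive (5015) gave 2179 with all 5 naive controls and 3884 to 5153 without 1 library. Anergic against HEL exposure (4425) gave 2497 with median-ratio scaling, 2366 with quantile normalization, 6857 with array weights, 2584 with voom, and 2800 (without anergic replicate 1) to 5292 without 1 library. Of genes called alike in both settings, 62 higher and 15 lower changed at least 2-fold, and lower ones ran from 147 (without CpG fl/- replicate 3) to 285 without 1 library. For the anergy sets, judged here by unadjusted camera p, the lower set with HEL (0.239) was at 0.149 with quantile normalization and 0.55 with 2-fold changes alone, and passed in both; the higher set with HEL was at -0.129 and passed with quantile normalization, and at -0.176 with 2-fold changes alone, where it did not; the lower set with CpG was at -0.002 with quantile normalization, lost its pass at 0.082 with an estimated correlation, was at 0.19 and passed with 2-fold changes alone, and ran from 0.036 to 0.146 without 1 library, losing its pass without fl/- replicate 2 or fl/+ replicate 2 or 4; the higher set with CpG ran from -0.088 to -0.058, gaining a pass without fl/- replicate 1 or fl/+ replicate 3, and was at -0.043 with 2-fold changes alone. Of the list tests 53 passed, and 1 with an estimated correlation. Over 347 gene results chosen by the naming rule and 7872 values, 7627 kept direction and side of the threshold, 211 lost their call, 32 gained one and 2 reversed: Ikzf3 with CpG ran from -0.17 to 0 (without fl/+ replicate 1), and S100a9 with CpG from -1.67 to 0.22 (without fl/+ replicate 4), neither past the threshold. No paired analysis was possible because the labels give no replicate numbers; the library-number block and the term for sex, which in naive cells sets 1 library per side against another and so acts like a pairing, rest on inferred groups. With 2 libraries on each side, the naive comparison recovered 82.1% of simulated 2-fold changes and 13.4% of 1.5-fold changes. Every simulated gene had the same dispersion of 0.02, so real genes with a larger spread can be missed at 2-fold too. Ikzf1, the deleted gene, did not pass at -1.05 in naive cells. Small changes there lie beyond this design.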

Other observations

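The values below were chosen after they were seen, and no test of an explanation was run. Among antigen receptor segments, which the naming rule leaves out, more kappa than heavy chain V segments were called in anergic cells, and the difference between chains was not tested. Of 21 kappa V segments tested against naive cells 11 were higher and 1 lower, with a median log2 difference of 1.31, while of 9 heavy chain V segments 0 were called by limma and 1 had a positive difference. The summed TPM of kappa V segments went the other way, at 2541, 2132 and 3451 in anergic cells against 7402, 6431 and 4148 in the naive controls, so more of the segments were higher while their total was lower. Against cells exposed to HEL for 1 day, 13 of 31 kappa V segments were higher and 2 lower, while 4 of 8 heavy chain V segments were lower and 0 higher, and the summed kappa V TPM was again below that of the HEL controls (3467 to 4327). With 1 day of HEL against naive, 7 of 15 kappa V segments were higher and 2 lower, and 2 of 9 heavy chain V segments were higher and 0 lower, with a median of 0. V segments are similar in sequence and MD4 encodes its own heavy and light chains; how reads were shared among segments was not tested, so the single segments are uncertain.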
